A study of Sus scrofa with 12 samples.

How the data were processed

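Oocytes of Sus scrofa were matured for 44 h in TCM199 medium to which gonadotropins, EGF and follicular fluid (10%) had been added, with or without glial cell line-derived neurotrophic factor (GDNF), and then stripped of cumulus cells with hyaluronidase and a pipette, per the labels' protocols. The oocytes belong to a class named SM or a class named LG, and the labels do not spell these names out. Total RNA was isolated with the PicoPure kit, amplified with the RiboAmp HS kit by oligo(dT) priming and 2 rounds of in vitro transcription, and labelled with Cy5 or Cy3 by the Universal Linkage System. Each of 12 arrays held a sample against a common reference of oocytes pooled from all groups. The series' design text gives 9 independently collected biological replicates per condition and 3 of them per array, while the labels give a number per pool of 2 for the samples and 16 for the reference. These numbers do not match and were used in no calculation. The p-values of single genes rest on the spread between these pools, while those of camera at its preset correlation rest on the spread between genes.

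The arrays lie on 3 slides, each with 1 array of every group. The sample carried Cy5 on slide 1, which holds the arrays of pool 1, and Cy3 on slides 2 and 3, per the labels. The sample's dye therefore runs with the slide, and slide 1 alone has the other orientation. The titles of LG GDNF 1 and LG GDNF 2, and of no other array, carry the word Clean. What it stands for is not known here, and it was used in no fit.

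The deposited values are log ratios of the authors, 1 per feature for 45220 features, treated here as log2 ratios. The base of the log, the channel in the numerator and the normalization are not given in the sources used here. The medians of the 12 arrays lay between -0.0106 and 0.0215 and the median absolute value was 0.267 on every array, so the deposited ratios had been centred and scaled between arrays. A high value of 14.17 makes base 10 improbable. No value was missing. Intensities, background and flags of the spots were not used here, so dim or saturated spots could not be set aside.

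Whether the deposited ratios had been turned to sample over reference could not be settled. A check correlated 3 independent contrasts within slide 1 with the same contrasts of slides 2 and 3 across features, and a mean above 0.05 was to mean that the ratios had been turned alike. The threshold was fixed before the data were examined, but not which 3 of the 4 contrasts between groups were to be used, which was settled after correlations had been seen. The set used left out LG against SM with GDNF (r = -0.246) and had a mean of 0.141. The other sets of 3 had means of 0.0607, -0.00128 and -0.0239, and all 4 contrasts 0.0440. With a mean between -0.05 and 0.05 the rule would have taken the ratios as Cy5 over Cy3 and turned slides 2 and 3. The contrasts of slide 2 with those of slide 3, which carry the same dye orientation, had means from -0.214 to -0.00125 over these sets, so the check cannot tell the orientation. The fit on the ratios as deposited and its opposite reading therefore have the same standing. Differences are given as sizes without a direction of expression. Beside the genes and lists of each comparison stand the fit on the 8 arrays of slides 2 and 3, which run the same way, and the opposite reading of these slides, mostly as a range over the genes named. The genes were chosen by their p in the ratios as deposited, which by itself favours that reading. All 58 differences of genes named by smallest p turned sign in the opposite reading, so within a comparison their sides relative to each other were kept.

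The platform annotation gave 1 gene symbol for 18121 features, none for 27099 and several for 0. Symbols were updated through RefSeq accessions without versions, which left the symbol of 2093 features and changed that of 116, then through current symbols for 15667 features and unique synonyms for 241, and 4 kept the file's name. The features of a gene were averaged, which gave 11912 genes, 3326 of them with more than 1 feature and 880 with a LOC placeholder.

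The genes were tested with limma (version 3.58.1, R 4.3.3): a linear model with the 4 groups and the slide, fitted to all 12 arrays, with empirical Bayes moderation and 6 residual degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes of a comparison, two-sided, and a gene counted as called at an adjusted p under 0.05. There were 7 comparisons. On simulated ratios with 200 changed genes among 11912, the fit called 59% of those changed by 1 on the log2 scale and 95% of those changed by 2 in the comparison of GDNF with control in SM. For GDNF against control in LG these shares were 53% and 95%, and for GDNF averaged over both classes 88% and 98%. With the changes added to the real ratios they were lower: 54% and 90% in SM, 50% and 91% in LG, and 82% and 96% averaged. In both runs the changes had the same orientation on all slides, which is not settled for the real data.

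Gene lists fixed before the data were examined, 15 in all, were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation beside it and with fry. They cover GDNF receptors and signalling, TGF-beta and BMP signalling, meiosis and M-phase, oocyte and maternal-effect genes, maternal mRNA polyadenylation and decay, chromatin and DNA methylation, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis and the pentose phosphate pathway, lipid and sterol metabolism, proteasome, antioxidants and heat shock, and apoptosis and DNA damage. Markers of cumulus and granulosa cells and of theca, stroma and blood form 2 further lists.

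Genes to be named were fixed by a rule. In GDNF against control in SM and in LG, LG against SM in controls, and the interaction, the rule takes up to 8 called genes per direction by size, filled up to 5 by smallest p where fewer are called. It takes 3 per direction in the other 3 comparisons and 4 members of each list called by camera. It always takes GDNF, GFRA1, RET, NCAM1, GDF9, BMP15, ZP3 and HAS2, while CYP19A1 and CCNB1 had no named feature and were not analysed here. Placeholders were skipped, between 1 and 3 among the 10 smallest p of a comparison. Alternatives covered the slide term, the dye, a block on pool number, both readings, the normalization, the summary of features, the filter, the moderation, array weights, the threshold and each array left out. Figures and spot clusters were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.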

Results

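Gene expression was measured in in vitro matured porcine oocytes of the classes SM and LG, each matured with or without GDNF, a ligand of the RET receptor kinase. There were 4 groups of 3 arrays, and each array compared a pool with a common reference. The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.196 on the log2 scale. The slide took 24.1% of the sum of squares over all genes. The group took 33.8% of what was left, against a median of 33.7% in 100 permutations of the groups within slides, of which 49 reached the observed share. These shares were computed in the ratios as deposited only. They do not cover the opposite reading. The sizes below are differences of deposited ratios on the log2 scale, taken as base 2, and carry no direction of expression because the orientation of the ratios is not settled. Genes said to lie on the same side or on opposite sides did so in the ratios as deposited. All 58 differences of genes named by smallest p kept their side on all 3 slides. A choice by p favours this outcome, so it is no separate support.

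The first question was how LG oocytes respond to GDNF. The smallest p belonged to GRB2, the adaptor that links receptor tyrosine kinases to RAS. Its difference between GDNF and control had a size of 1.26 with a standard error of 0.168, and lay on the same side on 3 of 3 slides. GRB2 is a member of the list of GDNF receptors and signalling, where 1 of 27 measured members passed when adjusted over the list alone (limma, adjusted p = 0.000877) and 0 passed over all genes (adjusted p = 0.387). On the 8 arrays of slides 2 and 3 the size was 1.40 (standard error 0.198, adjusted p = 0.0108 over the list alone), whereas in the opposite reading it was 0.61 and the adjusted p over the list alone was 0.487. The mean deposited ratio of GRB2 was 0.877 ± 0.324 (SD, n = 3) in LG control and -0.380 ± 0.126 (SD, n = 3) in LG GDNF. In SM the means were -0.197 ± 0.0683 (SD, n = 3) without and 0.217 ± 0.294 (SD, n = 3) with GDNF.

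**Figure D1:**
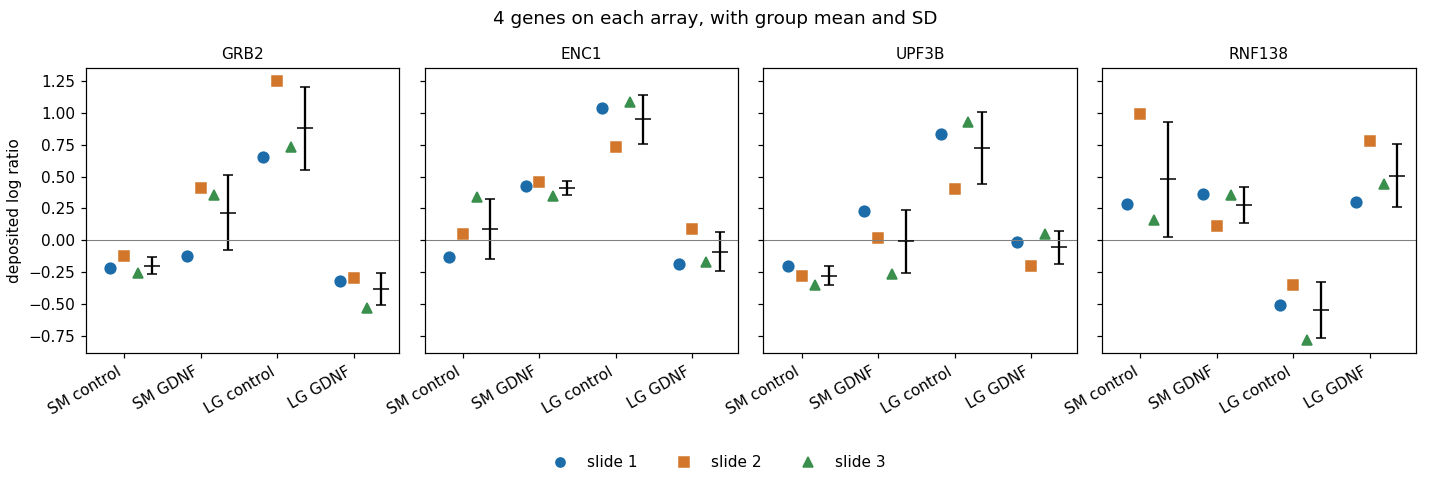
Deposited log ratio (vertical axis, taken as log2) of GRB2, ENC1, UPF3B and RNF138 on each of the 12 arrays by group, with symbols for the slide and a bar for the group mean ± SD (n = 3). In GRB2 the LG control arrays lie between 0.655 and 1.25 and the other 9 arrays at or below 0.413, and none of the 4 genes passed over all genes.

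Other genes with small p in this comparison did not pass the test either. On the side of GRB2 were ENC1, a kelch-repeat protein of the actin cytoskeleton, with a size of 1.04 (standard error 0.168), and UPF3B, a factor of nonsense-mediated mRNA decay, with 0.77 (0.170). The orphan nuclear receptor NR2F1 had 1.44 (0.348) and TPM4, a tropomyosin, 2.74 (0.655). The size of TPM4 leans on slide 3. Its deposited ratio was 2.91 on LG control 2, against 1.31 and 1.75 on the other arrays of that group. On LG GDNF 3 it was -2.26, against 0.221 and -0.196. On the opposite side were the ubiquitin ligase RNF138 with 1.05 (0.205), the ubiquitin-conjugating enzyme UBE2W with 0.81 (0.161), PIBF1 with 1.18 (0.240), the ciliary protein RPGR with 0.68 (0.140) and TRIML2 with 1.03 (0.221). The adjusted p of each of these 9 genes was 0.646 in limma, and each kept its side on 3 of 3 slides, which their choice by p favours. Their sizes lay between 0.70 and 3.56 on slides 2 and 3 alone. They lay in the opposite reading between 0.13 (UBE2W) and 2.01 (TPM4), with ENC1 at 0.22, and none had an unadjusted p under 0.05 (smallest 0.0611). Over all genes limma called 0 of 11912, while 902 had an unadjusted p under 0.05 against 595.6 by chance. On slides 2 and 3 alone 611 genes did so, in the opposite reading 570, without LG GDNF 2 only 476, and with array weights 2043.

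Cytosolic ribosomal protein genes moved together between GDNF and control in LG, with a median size of 0.32 and 39 of 48 measured members on the same side (camera adjusted p = 0.0025 at the preset correlation). The adjusted p was 0.886 with an estimated correlation. The estimate was 0.515 for this list and 0.0776 for the meiosis list below, against the preset 0.01. Slide 1 ran the other way as deposited: the list medians of LG control and LG GDNF were -0.0785 and 0.0383 there. They were 0.813 and 0.371 on slide 2 and -0.586 and -1.38 on slide 3. None of the ribosomal members passed over all genes: RPL23A had a size of 1.57 (standard error 0.508), RPS3 0.86 (0.331), RPS19 1.12 (0.469) and FAU 1.42 (0.694). Meiosis and M-phase genes moved to the opposite side, with a median size of 0.16 and 27 of 39 members on that side (camera adjusted p = 0.0025, and adjusted p = 0.886 with an estimated correlation). Among them the spindle checkpoint gene MAD2L1 had 1.99 (0.621), cyclin E1 (CCNE1) 1.12 (0.379), the anaphase-promoting complex inhibitor FBXO43 1.34 (0.508) and CKS2 0.82 (0.339). Without LG GDNF 3 both calls ended (adjusted p = 0.756 for ribosomal proteins, which turned to the other side, and 0.0755 for meiosis), and without LG control 3 the ribosomal call ended (adjusted p = 0.842). Without LG GDNF 3 RPS19 had 0.73 and FAU 0.615, and without LG control 2 CCNE1 had 0.64. In the opposite reading the meiosis call ended (median size 0.08, adjusted p = 0.144) and the ribosomal list was called (0.49, adjusted p = 2.4e-07), as were oxidative phosphorylation (0.23, 0.00047) and proteasome genes (0.26, 0.0109), each with an adjusted p of 0.451 with an estimated correlation. The 8 members named had sizes between 0.19 and 1.33 in that reading. Both lists stayed called on slides 2 and 3, and oxidative phosphorylation was called beside them (0.25, adjusted p = 0.0114, and adjusted p = 0.716 with an estimated correlation).

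LG GDNF 3 and LG control 2, both on slide 3, stood apart in these genes. Their median deposited ratio of ribosomal protein genes was -1.38 and -0.586, while the other 6 arrays of slides 2 and 3 lay between 0.275 and 0.813. The cumulus and granulosa list had medians of -0.191 and -0.155 on these arrays against -0.0156 to 0.152 on the other 6. The oocyte and maternal-effect list had 0.569 and 0.170 against -0.232 to 0.315. LG control 2 also had the widest spread of the 12 arrays, with an SD of 0.871 and 489 features above a ratio of 4. LG GDNF 3 lacks the word Clean, which the titles of LG GDNF 1 and LG GDNF 2 carry. Whether this mark reflects a difference in handling was not tested.

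**Figure D2:**
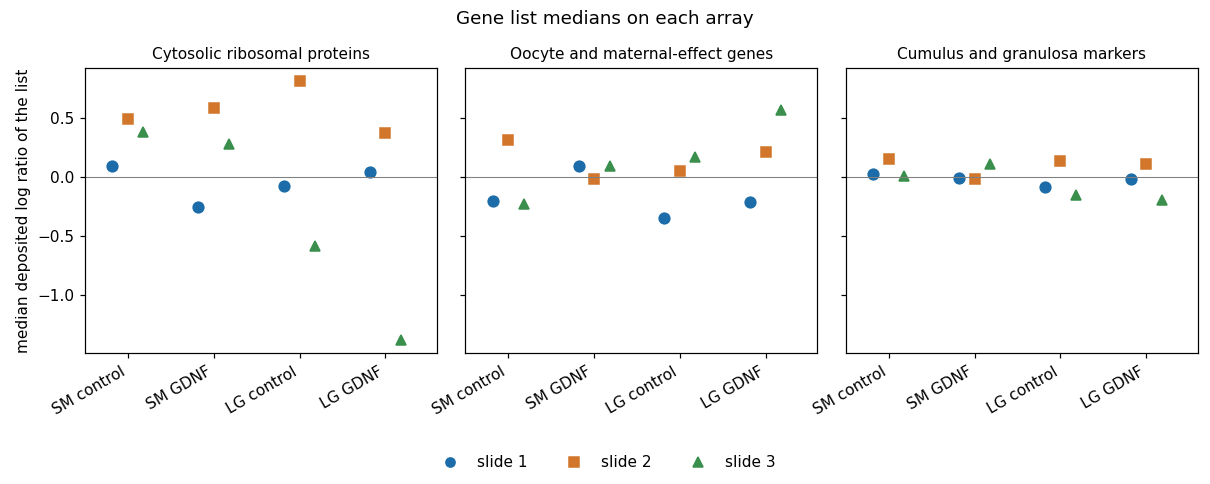
Median deposited log ratio (vertical axis, taken as log2) over the measured members of 3 gene lists on each of the 12 arrays by group, with symbols for the slide. The ribosomal protein medians of LG control 2 (-0.586) and LG GDNF 3 (-1.38) lie below those of the other 10 arrays.

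In SM oocytes no gene passed between GDNF and control. The smallest p belonged to CCDC80, with a size of 1.06 (standard error 0.193), SRL (sarcalumenin, a calcium-binding protein) with 0.79 (0.145) and LRRC40 with 0.99 (0.183). CCDC80 and SRL lay on the same side, as did PNMA2 with 0.57 (0.142), the fatty acid hydroxylase CYP4F2 with 0.68 (0.173) and syntabulin (SYBU) with 0.56 (0.142). LRRC40 lay on the opposite side, with the ferric reductase-like FRRS1 at 0.66 (0.169), the neuropeptide NMS at 0.54 (0.143), the transducin subunit GNAT2 at 0.58 (0.165) and the peptidoglycan sensor NOD1 at 0.82 (0.238). These 10 sizes lay between 0.445 and 1.01 on slides 2 and 3 alone. The opposite reading put them between 0.0052 (FRRS1) and 0.33 (PNMA2), with CCDC80 at 0.28 and SRL at 0.10, and none had an unadjusted p under 0.05 (smallest 0.206). Each of the 10 genes kept its side on 3 of 3 slides, which their choice by p favours. Limma called 0 of 11912 genes, with 279 at an unadjusted p under 0.05 against 595.6 by chance. On slides 2 and 3 alone 140 genes had such a p, in the opposite reading 250, without SM control 2 the number was 473 and without SM GDNF 3 it was 689. No list was called by camera in either reading or on slides 2 and 3: as deposited, oocyte and maternal-effect genes had a median size of 0.11 over 23 members (adjusted p = 0.755) and cumulus and granulosa markers 0.024 over 25 (adjusted p = 0.970).

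The receptor genes of GDNF did not pass between GDNF and control. GFRA1, the co-receptor, had a size of 0.24 (standard error 0.18) in SM and 0.23 (0.18) in LG, and RET had 0.19 (0.221) and 0.00 (0.221). NCAM1, an alternative receptor, had 0.26 (0.510) in SM and 1.20 (0.510) in LG (limma, adjusted p = 0.649). The value in LG was 0.53 without LG GDNF 3, whose deposited ratio was -2.15 against 0.0389 and 0.87 on the other arrays of its group, and 0.85 without LG control 3. GDNF itself had 0.19 (0.201) and 0.24 (0.201). Among oocyte genes ZP3, a zona pellucida protein, had 0.73 (0.307) in SM and 0.07 (0.307) in LG, GDF9 had 0.70 (0.726) and 0.32 (0.726), and BMP15 had 0.13 (0.459) and 0.40 (0.459). The hyaluronan synthase HAS2 had 0.06 (0.274) in SM and 0.46 (0.274) in LG. In LG these values also lean on LG GDNF 3. HAS2 was at -0.731 on it, against 0.400 and 0.419 on the other arrays of its group, and BMP15 at 1.12, against -0.818 and -0.118. The differences of GFRA1, NCAM1, ZP3, GDF9 and HAS2 lay on opposite sides in SM and LG, and those of GDNF and BMP15 on the same side. None of these genes passed over all genes or adjusted over the list alone. In the opposite reading NCAM1 had 0.96 in LG and RET 0.45 in LG (limma, unadjusted p = 0.0316). BMP15 had 0.69 in both classes (unadjusted p 0.036 in SM and 0.0365 in LG), but on opposite sides in that reading. Its interaction there had a size of 1.38. The other values were at most 0.75. The sizes of the 8 genes on slides 2 and 3 lay between 0.03 and 0.66 in SM and between 0.205 and 1.61 in LG, with 0 at an unadjusted p under 0.05. In the other comparisons the opposite reading put 1 of the 8 under that p in controls, 1 for LG against SM with GDNF, 2 in the interaction and 1 in averaged class. Between LG and SM with GDNF, BMP15 had 1.25 in that reading (limma, unadjusted p = 0.00158, adjusted p = 0.972), against 0.43 as deposited.

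Whether the response to GDNF differs between the classes was tested as an interaction. GRB2 had the smallest p, with a size of 1.67 (standard error 0.238), on the same side on 3 of 3 slides. It passed adjusted over the list alone (1 of 27 members, limma adjusted p = 0.00144) but not over all genes (adjusted p = 0.635). The adjusted p over the list alone was 0.0110 on slides 2 and 3 and 0.582 in the opposite reading. With GRB2 lay ENC1 at 1.37 (0.238), PID1 at 1.02 (0.225), FRRS1 at 1.07 (0.239) and UPF3B at 1.05 (0.240). SRL at 1.04 (0.206), PNMA2 at 0.88 (0.201), UBE2W at 0.99 (0.227), RNF138 at 1.25 (0.289) and CCDC61 at 1.20 (0.284) lay on the opposite side. The sizes of these 9 genes lay between 0.78 and 1.62 on slides 2 and 3. The opposite reading put them between 0.05 (UBE2W) and 0.97 (CCDC61), with ENC1 at 0.17, FRRS1 at 0.22 and GRB2 at 0.96, and only CCDC61 had an unadjusted p under 0.05 (0.0406). Limma called 0 genes, with 499 at an unadjusted p under 0.05, against 523 in the opposite reading, 410 on slides 2 and 3, 787 without SM GDNF 2 and 325 without LG GDNF 2. Camera called no list in the ratios as deposited. It called ribosomal proteins in the opposite reading (median size 0.58, adjusted p = 1.3e-05, and adjusted p = 0.754 with an estimated correlation). On slides 2 and 3 it called ribosomal proteins (0.62, adjusted p = 0.000633) and meiosis genes (0.17, 0.0213), both with an adjusted p of 0.775 with an estimated correlation. Across genes, which are not independent replicates, the GDNF differences in SM and LG correlated at r = 0.0459, and 100 permutations within slides gave -0.464 to 0.460, 47 of them as high. This correlation was computed in the ratios as deposited only.

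The classes were next compared without GDNF. GRB2 differed between LG and SM controls with a size of 1.07 (standard error 0.168), which passed adjusted over the list alone (1 of 27, limma adjusted p = 0.00304) and not over all genes (adjusted p = 0.673). On slides 2 and 3 the adjusted p over the list alone was 0.0274, and in the opposite reading 0.869. This comparison, GDNF against control in LG and the interaction share the LG control arrays, so the values of GRB2 in them are not independent. On the side of GRB2 were UPF3B at 1.00 (0.170), ENC1 at 0.86 (0.168), PID1 at 0.79 (0.159) and FRRS1 at 0.73 (0.169). UBE2W at 0.87 (0.161), the tetraspanin CD82 at 0.79 (0.147), the Polycomb ubiquitin ligase RNF2 at 0.73 (0.143), RNF138 at 1.02 (0.205) and the transcription factor subunit TAF9 at 1.10 (0.230) lay on the opposite side. The 9 sizes lay between 0.67 and 1.24 on slides 2 and 3. For the opposite reading the range was 0.08 (ENC1) to 0.54 (TAF9), GRB2 had 0.49, and none had an unadjusted p under 0.05 (smallest 0.213). None of these genes passed over all genes, where limma called 0 and 846 had an unadjusted p under 0.05, against 461 in the opposite reading and 534 on slides 2 and 3. No list was called in either reading or on slides 2 and 3: as deposited, markers of cumulus and granulosa cells had a median size of 0.051 (adjusted p = 0.417) and those of theca, stroma and blood 0.072 (adjusted p = 0.564).

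With GDNF, camera at its preset correlation called 4 lists between LG and SM oocytes in the ratios as deposited, which moved to the same side. Ribosomal protein genes had a median size of 0.44 (46 of 48 members on that side, camera adjusted p = 1.9e-08), oxidative phosphorylation genes 0.22 (43 of 49 members, 6.5e-07), proteasome genes 0.14 (21 of 29 members, 0.00823) and lipid and sterol genes 0.11 (19 of 28 members, 0.0447). The adjusted p was 0.432 with an estimated correlation for each of the 4 lists. The estimates were 0.515, 0.292, 0.152 and 0.0443 in this order, each above the preset 0.01. The calls therefore rest on a correlation between genes lower than these data show. In the opposite reading the ribosomal (0.69, adjusted p = 6.7e-14) and oxidative phosphorylation lists (0.18, 0.00184) were called, and the lipid (0.0135, 0.216) and proteasome calls (0.10, 0.199) ended. That reading called 4 further lists, oocyte and maternal-effect genes (0.34, 0.00184), meiosis (0.16, 0.0129), cumulus and granulosa markers (0.05, 0.0431) and maternal mRNA polyadenylation and decay (0.08, 0.0431), none with an adjusted p under 0.436 with an estimated correlation. The 4 lists stayed called on slides 2 and 3, beside oocyte (adjusted p = 0.00564), meiosis and cumulus (0.0141) and GDNF signalling genes (0.0227), none with an adjusted p under 0.348 with an estimated correlation. Members of the ribosomal list were RPL19 at 0.82 (standard error 0.398), RPL7 at 0.63 (0.367), RPL4 at 0.56 (0.337) and RPS18 at 0.88 (0.534). Cytochrome c (CYCS) at 0.92 (0.330) and the complex I subunits NDUFB11 at 0.49 (0.18), NDUFA8 at 0.77 (0.302) and NDUFA7 at 0.94 (0.419) represent oxidative phosphorylation. The proteasome genes PSMC5 at 0.82 (0.462), PSMB7 at 0.42 (0.241), PSMB4 at 0.48 (0.286) and PSME2 at 0.88 (0.532) and the lipid genes PPARG at 0.68 (0.175), CPT1A at 0.30 (0.185), HADHB at 0.38 (0.271) and FDPS at 0.19 (0.161) did not pass either. These 16 sizes lay between 0.03 (FDPS) and 1.09 (PSME2) in the opposite reading. Without LG GDNF 3 RPL19 had 0.38, RPL7 0.09, RPL4 0.13, RPS18 0.18, NDUFA8 0.46, NDUFA7 0.61, HADHB 0.185 and CPT1A 0.08, and the 4 proteasome genes lay between 0.115 and 0.155. HADHB had 0.15 without SM GDNF 1. All 4 calls ended without LG GDNF 3, the array with the ribosomal median of -1.38 (each adjusted p = 0.842), and without SM GDNF 2 (adjusted p = 0.194 for ribosomal, 0.126 for oxidative phosphorylation and 0.405 for proteasome and lipid genes). The proteasome and lipid calls also ended without SM GDNF 1 (adjusted p = 0.0789), and the lipid call without SM control 1 (0.0561), SM control 3 (0.0520) or LG control 3 (0.0511). Single genes with the smallest p were CCDC82 at 0.76 (0.149), the ESCRT-III protein CHMP4A at 0.88 (0.203) and UBL3 at 1.08 (0.261), opposite to the RNA-editing enzyme APOBEC1 at 0.79 (0.195), TMEM154 at 0.51 (0.131) and SLC9A3R2 at 0.55 (0.146). These 6 sizes lay between 0.53 and 1.09 on slides 2 and 3, and between 0.155 and 0.37 in the opposite reading (smallest unadjusted p 0.223). Limma called 0 genes, with 287 at an unadjusted p under 0.05, against 490 in the opposite reading, 213 on slides 2 and 3 and 653 without SM GDNF 3.

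The averaged comparisons set 6 arrays against 6. For GDNF over both classes limma called 0 genes, with 530 at an unadjusted p under 0.05, 223 in the opposite reading and 195 on slides 2 and 3. As deposited, LRRC40 at 0.59 (standard error 0.130), GNAT2 at 0.50 (0.117) and RPGR at 0.40 (0.0988) lay opposite to CCDC80 at 0.61 (0.137), the collagen receptor DDR2 at 0.39 (0.0920) and the histone deacetylase HDAC5 at 0.41 (0.101). These 6 sizes lay between 0.36 and 0.59 on slides 2 and 3, and between 0.07 and 0.17 in the opposite reading (smallest unadjusted p 0.474). Ribosomal proteins (median size 0.21) and meiosis genes (0.15) moved to opposite sides (camera adjusted p = 0.00366 for both, and adjusted p = 0.993 with an estimated correlation). Both calls ended without LG GDNF 3 (adjusted p = 0.874 for ribosomal and 0.0607 for meiosis genes), SM control 3 (0.873 and 0.0907) or SM GDNF 1 (0.215 for both), and the ribosomal call without SM GDNF 3 (0.108) or LG control 3 (0.350). The meiosis call also ended in the opposite reading (0.880) and on slides 2 and 3 (0.0516). The opposite reading called ribosomal proteins (median size 0.22, adjusted p = 0.00119) with oxidative phosphorylation (0.14, 0.00119), antioxidant (0.13, 0.0019), proteasome (0.18, 0.0155) and theca, stroma and blood genes (0.12, 0.0377), none with an adjusted p under 0.577 with an estimated correlation. Without single arrays the count of 530 became 303 (SM control 1), 913 (SM control 2), 293 (SM control 3), 317 (SM GDNF 1), 305 (SM GDNF 2), 1314 (SM GDNF 3) or 334 (LG GDNF 2). For LG against SM over both treatments limma called 0 genes, with 475 at an unadjusted p under 0.05, 362 in the opposite reading, 297 on slides 2 and 3, 268 without SM GDNF 2 and 1167 without SM GDNF 3. CRABP2, which binds retinoic acid, at 0.77 (0.145), the F-box protein SKP2 at 0.45 (0.0923) and SLC25A16 at 0.42 (0.0948) lay opposite to the calcineurin subunit PPP3CC at 0.58 (0.139), TAF9 at 0.66 (0.163) and RNF2 at 0.41 (0.101). The 6 sizes lay between 0.42 and 0.63 on slides 2 and 3, and in the opposite reading between 0.04 and 0.19 (smallest unadjusted p 0.257). Ribosomal proteins (0.33), oxidative phosphorylation (0.23), proteasome (0.15) and lipid genes (0.11) moved to the same side, with camera adjusted p of 1.0e-06 for the first 2 lists and 0.0131 for the others, and adjusted p = 0.586 with an estimated correlation for each. Without LG GDNF 3 the ribosomal (adjusted p = 0.0530), lipid (0.182) and proteasome (0.252) calls ended. So did the ribosomal and lipid calls without SM control 3 (0.0602), the lipid and proteasome calls without SM GDNF 2 (0.0574 and 0.0879) and without LG control 1 (0.107 and 0.265). The lipid and proteasome calls ended too in the opposite reading (0.574 and 0.944) and on slides 2 and 3 (0.0614 and 0.128). The opposite reading called ribosomal proteins (0.40, adjusted p = 4.2e-10), oxidative phosphorylation (0.08, 0.0487) and oocyte and maternal-effect genes (0.29, 3.1e-05), none with an adjusted p under 0.297 with an estimated correlation. Slides 2 and 3 called ribosomal and oxidative phosphorylation genes, beside oocyte (adjusted p = 0.000277), cumulus (0.0208) and glycolysis genes (0.0476), each with an adjusted p of 0.655 with an estimated correlation.

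In the ratios as deposited the other fixed lists were called by camera in none of the 7 comparisons. The lowest adjusted p over the comparisons came from LG against SM with GDNF for antioxidant and heat shock genes (0.0557, median size 0.12), GDNF receptors and signalling (0.0677, 0.10), cumulus and granulosa markers (0.0770, 0.11) and glycolysis and pentose phosphate genes (0.0891, 0.10). In the same comparison it was 0.282 for chromatin and DNA methylation, 0.361 for TGF-beta and BMP signalling and 0.644 for maternal mRNA polyadenylation and decay. For LG against SM over both treatments it was 0.146 for apoptosis and DNA damage, 0.166 for oocyte and maternal-effect genes and 0.542 for theca, stroma and blood markers. Adjusted over the list alone, 0 members of these lists passed except GRB2, and over all genes 0. Fry's test of change in either direction passed in 1 list, GDNF receptors and signalling, with an adjusted p of 4.3e-05 for GDNF in LG, 0.00509 for LG against SM in controls and 0.0012 for the interaction. In the other lists it was at least 0.203. Without GRB2, left out after its values were seen, it was 0.0129, 0.467 and 0.756, and in the opposite reading 0.355, 0.900 and 0.583. Without SM control 2 it was 0.595 in controls and 0.0798 for the interaction, and without LG control 1 0.0921 in controls.

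The opposite reading had other leading genes, named here after their values were seen. The smallest p belonged to GPD2, the mitochondrial glycerol-3-phosphate dehydrogenase, for GDNF in SM (size 0.70, standard error 0.135), for LG against SM with GDNF (0.74, 0.135) and for the interaction (1.04, 0.192). STRBP had the smallest p for GDNF in LG (0.71, 0.125) and asparagine synthetase (ASNS) for LG against SM in controls (1.89, 0.333). CCDC103 at 0.42 (0.0972) and ZFAND3 at 0.69 (0.143) led the averaged comparisons of GDNF and of class. None passed over all genes in limma, and as deposited their sizes in the same comparisons were between 0.04 and 0.85. Of the 105 tests of a list in a comparison, camera called 12 as deposited and 18 in the opposite reading, 6 of them in both.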

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

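The tests of single explanations in this part were chosen after the values of GRB2 had been seen; the list that holds GRB2 was fixed before.

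GRB2 stood out because the response to GDNF differed between LG and SM in the interaction test, adjusted over the list of GDNF receptors and signalling alone (adjusted p = 0.00144). It was the only gene to pass in this way in 105 tests of a list in a comparison, namely in 3 comparisons that share the LG control arrays. The reading of slide 1 is not its only source, since GRB2 ranked 1 of 11912 genes by p on slides 2 and 3 alone, although the opposite reading ended the call. Chance among the genes tested stays open, with an adjusted p of 0.387 over all genes in LG. In the ratios as deposited no single array carried the call over the list alone. With each array left out in turn, limma's adjusted p over the list was at most 0.00937 for GDNF in LG, 0.0251 for LG against SM in controls and 0.00827 for the interaction. GRB2 is measured by 1 feature, so no second feature can check it. The smallest contrast of GDNF with control over the 3 slides (0.972, against a residual SD of 0.344 for a difference of 2 arrays) does not by itself decide on a spot artifact on a single array. Of the 10 genes of smallest p in LG, among which GRB2 was chosen, 10 had 1 sign on the 3 slides and 0 had a contrast under that SD. This choice also favours the values with an array left out. It favours the rank on slides 2 and 3 too, since these arrays are part of the fit that chose GRB2. Of the 10 genes, 1 was among the 10 smallest p there, in a fit with 3 residual degrees of freedom.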

How the results depend on the processing

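The fits without LG control 2 and LG GDNF 3 and without locally bright features, the list and gene values on slides 2 and 3, fry without GRB2, and the other sets of contrasts in the orientation check were chosen after seeing the data. In all 7 comparisons the count of called genes was 0 under every alternative but an unadjusted p under 0.01, leaving out each array included (range 0 to 0). At that threshold the counts were 30 for GDNF in SM, 152 for GDNF in LG, 170 for LG against SM in controls, 36 with GDNF, 68 for the interaction and 54 for both averaged comparisons. The lowest adjusted p under any setting was 0.0611, with array weights. With these weights the counts at an unadjusted p under 0.05 also rose to 515 for GDNF in SM, 2043 for GDNF in LG, 1290 for LG against SM in controls, 891 for the interaction, 1593 for averaged GDNF and 776 for averaged class. The filter for missing values moved nothing, since no value was missing, and has no value of its own.

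With pool number as a replicate block, in place of the slide or together with it, the count of called genes stayed at 0. Deviations of arrays with the same pool number correlated between -0.501 and 0.403 over the pairs of groups compared, with 0.0978, 0.295 and 0.403 between SM control and SM GDNF. A correlation over 0.1 in every pair was needed to take the numbers as a pairing, which none of the 4 pairs of groups compared reached. SM control and LG GDNF, not compared, reached it (0.427, 0.575 and 0.131), but there each number shares a slide, so number and slide cannot be told apart. In no pair of groups did all 6 arrays correlate best with their own number. As a hint from the data, not the design, values with the same number on different slides correlated between 0.601 and 0.764 (0.15 to 0.314 in 4 pairs with LG control 2 or LG GDNF 3), against at most 0.603 across groups, numbers and slides. Of the 12 lists called by camera, 11 stayed called with the block and 12 with quantile normalization, and 0 with an estimated correlation or with fry's directional test. The test in either direction lost 2 of its 3 calls with the block (0.078 and 0.0597). On slides 2 and 3 alone 9 stayed called. Without SM GDNF 2 the number was 6, and without LG GDNF 3 it was 1.

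The opposite reading of slides 2 and 3 reversed all 12 lists. Its adjusted p for ribosomal proteins was 2.4e-07 for GDNF in LG, 6.7e-14 for LG against SM with GDNF, 0.00119 for averaged GDNF and 4.2e-10 for averaged class. For meiosis it was 0.144 for GDNF in LG and 0.880 for averaged GDNF. For LG against SM with GDNF it was 0.216 for lipid, 0.00184 for oxidative phosphorylation and 0.199 for proteasome genes, and for averaged class 0.574, 0.0487 and 0.944. This follows from turning the sign of slides 2 and 3. Without both LG control 2 and LG GDNF 3 only 2 of the 12 lists stayed called, and 8 kept their side but were no longer called. Ribosomal proteins reversed there for LG against SM with GDNF (camera adjusted p = 0.541) and averaged class (0.153), and without LG GDNF 3 for GDNF in LG (0.756). Over the arrays left out the last of these ranged from 7.0e-09 to 0.842. The cause was not tested beyond the arrays left out.

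The orientation check gave 0.213 among the features of highest variance with the 3 contrasts used and 0.0716 with all 4. Over all features it gave 0.0440 with all 4 contrasts, and 0.0607, -0.00128 and -0.0239 with the other sets of 3, because LG against SM with GDNF, which these hold, had r = -0.246. The correlation of the GDNF differences in SM and LG was 0.147 after quantile normalization and 0.127 without both arrays. Of 162 named gene values, the sign turned in 138 in the opposite reading, in 4 after quantile normalization and in 0 without the slide term. Spot intensities were not used here, so limits from signal over background are unknown.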

Other observations

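The tests of explanations in this part were chosen after the patterns were seen, as were the 3 contrasts of the orientation check of slide 1, whose threshold was set earlier.

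On the deposited scale LG GDNF 3 and LG control 2 lay outside the range of the other 6 arrays of slides 2 and 3 in some cumulus genes and a few others, named here after their values were seen and given without a direction of expression. TNFAIP6, which cross-links the cumulus matrix, was at -2.08 and -0.469 on these arrays and between 1.36 and 2.26 on the other 6. The glutathione transferase GSTA1 was at -1.89 and -1.41, against 0.787 to 2.46, and the matrix proteoglycan VCAN at -1.51 and 0.0719, against 0.473 to 1.55. Over the 25 measured cumulus and granulosa genes the median moved less, at -0.191 and -0.155 against -0.0156 to 0.152. How many of these genes lay outside the range was not counted. Vimentin (VIM), from the list of theca, stroma and blood, was at -2.11 and -1.64, against -0.0295 to 1.91. MOS, the kinase of meiotic arrest, lay on the other side at 2.30 and 3.52, against -0.372 to 0.473. Of the other oocyte genes, GDF9, ZAR1 and BMP15 lay outside the range of the other 6 on 1 of these arrays each. On LG control 2 GDF9 (2.84) and ZAR1 (2.43) lay above the other 6 (at most 1.53 and 1.49), on the side of MOS, and on LG GDNF 3 within their range (1.15 and 1.47). BMP15 lay above them on LG GDNF 3 (1.12, against at most -0.118) and within their range on LG control 2 (-0.375). ZP3 lay within it on both (0.909 and 0.724).

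The LG control group had the most genes that set its arrays apart. In 210 genes the 3 LG control arrays lay beyond the other 9, all above or all below, against 77 genes for SM control, 57 for SM GDNF and 61 for LG GDNF. Of the 64 sets of 1 array per slide, 3 had as many as LG control, itself included, with a median of 68 over the other sets and a highest of 272. In the opposite reading LG control had 31 such genes, and 34 sets had as many. The slide was not removed in these counts. Arrays of slide 1 correlated with those of slides 2 and 3 (median r = 0.399), so turning the latter by itself sets the slides apart. The drop from 210 to 31 therefore says little about LG control.

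LG control 2 and LG GDNF 3 stand apart in ribosomal protein genes. A shift of slide 3 or its dye is argued against, since the lower ribosomal median of its SM arrays was 0.275, above 0. LG GDNF 3 held 5 clustered high features, where shuffled values gave 0.02, and LG control 2 held 40 (48.4 if shuffled). Of the 48 ribosomal protein genes, 0 had a feature in a cluster on either array. This cannot decide on locally bright areas as the source. Only deviations over 2 counted, and the high clusters held just 15 features with a gene symbol on LG control 2 and 3 on LG GDNF 3. A candidate explanation is a different share of RNA from cumulus cells, since the cumulus and granulosa list lay outside the range of the other 6 arrays on both (-0.155 for the nearer array) and the oocyte list lay on the other side of their mean (0.569 and 0.170, mean 0.0718), though for LG control 2 within their range, and single oocyte genes lay on the side of MOS or within that range. Of the 25 measured cumulus and granulosa genes, 3 are also in another fixed list. The shift was not particular to that list. Oxidative phosphorylation genes also lay below the other 6 arrays on both (-0.0407 on LG control 2 and -0.427 on LG GDNF 3, against 0.144 to 0.5). So did glycolysis (-0.285 and -0.215) and lipid genes (-0.104 and -0.196). Theca, stroma and blood markers did so on LG GDNF 3 (-0.118) but not on LG control 2 (0.0477). RNA from cumulus cells remains a hypothesis, since the oocytes were denuded per the labels and the 2 arrays were picked for standing apart, and a difference between the pools themselves was not tested.

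The shared profile of slide 1 with slides 2 and 3 (median r = 0.399 between their arrays) leaves open how the ratios were deposited. Ratios of Cy5 over Cy3 would make contrasts of slide 1 run against those of slides 2 and 3, and the mean correlation was 0.141 over the 3 contrasts used, 0.0440 over all 4 and as low as -0.0239 over another set of 3. Slides 2 and 3 themselves gave -0.0976 over the contrasts used, so the bound of 0.05 was wrong for these data and could not decide. Ratios already turned to sample over reference would turn bright spots of a single dye, yet spot clusters had high ratios on 1 array of slide 1 and 5 arrays of slides 2 and 3 and low ratios on 0, apart from LG control 2, and 1 array is too few. These readings cannot be told apart.

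Other splits of the arrays, made in the ratios as deposited only, gave the following counts of genes at an unadjusted p under 0.05. With 10 splits of 6 arrays a share under 0.05 cannot be reached. The real count was 279 for GDNF in SM, with 8 splits as large and a highest other of 1513, and 902 for GDNF in LG, with 1 split as large, the real one, and a highest other of 820. It was 846 for LG against SM in controls, with 3 splits as large and a highest other of 1014, and 287 with GDNF, with 8 splits as large and a highest other of 857. Of 100 drawn splits of the 12 arrays, 59 gave as many as the 499 of the interaction (highest other 1857), 47 as many as the 530 of averaged GDNF (1998) and 49 as many as the 475 of averaged class (1667), so chance is not excluded for these. These splits cross slides, whereas each slide holds 1 array of every group. In 100 splits made within slides, 24 gave as many as the interaction (highest other 1966), 27 as many as averaged GDNF (1949) and 48 as many as averaged class (1949). In the comparisons of 2 groups only 4 splits keep the slides, and the highest other was 1513 for GDNF in SM, 717 for GDNF in LG, 1014 for LG against SM in controls and 857 with GDNF. At an adjusted p under 0.05, against 0 for the real groups, the highest other splits across slides called 315 genes for averaged GDNF, 5 for the interaction and 7 for averaged class. Within slides they called 205 for the interaction and 111 for both averaged comparisons. Each is the highest of its splits, and how high such a count comes by chance was not tested. A structure of the arrays that follows neither treatment nor class alone is therefore only a possibility. The side of the split with 315 genes, picked for its count, holds all 3 LG control arrays, all 4 arrays of pool number 3 and 3 of the 4 arrays of slide 3. With pool number as a block this split called 550 genes in place of the slide and 243 together with it.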
